A study of Mus musculus with 3 samples.

How the data were processed

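The series profiled mRNA in CT26, a mouse colon carcinoma line that grows in culture in medium with 10% fetal bovine serum. Cells had been stably transfected with a puromycin- and GFP-carrying vector that held either a control microRNA or the miR-17~92 cluster, then selected with puromycin, sorted for GFP and grown from single cells. The labels name 3 groups: miR-Ctrl (here Ctrl), miR-17~92Med (Med, medium levels of the cluster) and miR-17~92Hi (Hi, high levels). The design text speaks of 3 subclones in each group, while 1 value column stands for each group. Whether a column is a single subclone, pooled RNA or a mean of arrays is not given in the sources used here. Each group therefore entered as 1 sample, and no SD, SE or p-value was computed.

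Per the labels' protocols, 100 ng of total RNA was amplified with random primers, biotinylated and hybridized to an Affymetrix array. The deposited table holds 35556 probe sets. Per the submitters' processing notes, Affymetrix Expression Console and GCRMA, a background correction and normalization method for such arrays, are named, with no role, order or version given. The deposited values are on a log2 scale as taken from their range of 2.13 to 14.8, since the base is not given in the sources used here. Any normalization between arrays, the summary of probes and the pooling of subclones came before deposit. A difference of log2 values between columns cannot separate such steps from the cells.

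Gene symbols came from GEO's annotation of the platform, updated through gene numbers to RefSeq's gene table of the mouse assembly GRCm38.p6. That table was used for names and gene order and no coordinates are printed. Of the probe sets, 21789 were listed under 1 gene, 1621 under several and 12146 under none. Of the single-gene probe sets, 21698 (99.6%) were matched by gene number. Probe sets of several genes named no gene. Probe sets of 1 gene were averaged, which applied to 999 genes with over 1 probe set and gave 19938 genes. Genes whose mean over the 3 columns reached the median of all genes, 7.13, passed the expression filter (9969 genes). No per-sample column was left unmapped (0).

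The comparisons were Med against Ctrl, Hi against Ctrl and Hi against Med. In each, genes with a log2 difference of 1 or more (2-fold) were counted per direction. For genes 2-fold apart between Hi and Ctrl, the place of Med was recorded. A planned benchmark from a random order of the columns is not given, because these genes are selected on Hi and Ctrl and many values are tied. Olfactory and vomeronasal receptor genes, which a colon carcinoma line is not known to use, served as a gauge of noise. The overlap and correlation of the 2 comparisons that share the Ctrl column were set beside independent lists and beside simulated unchanged columns.

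There were 30 gene lists with 688 distinct genes, written from general knowledge before the data were examined, of which 62 genes were not matched to a single-gene probe set and are not analysed here. They covered the miR-17~92 locus and its paralogous host genes, reported miR-17~92 targets, microRNA biogenesis, DNA replication, mitosis, p53 response, apoptosis, TGF-beta, PI3K-AKT-mTOR, extracellular matrix, mesenchymal, epithelial and intestinal genes, matrix proteases and motility, angiogenesis, hypoxia and glycolysis, interferon response, antigen presentation, NK cell ligands, chemokines and NF-kB responses, Wnt, MAPK and immediate-early genes, Myc targets, ribosomal proteins, cholesterol and fatty acid synthesis, ER stress and amino acid response, oxidative phosphorylation, oxidative stress and drug efflux, immune cell markers, endothelial and fibroblast markers, and housekeeping genes. The median difference of each list's members past the filter was placed among 10000 random lists of the same size, matched on mean level in 20 bins. A list outside the central 95% (percentiles 2.5 to 97.5) is described as standing apart. Lists with under 5 members past the filter have values only. The percentile describes these 3 columns and is no test of a condition. An additional pair of lists (slowly evolving housekeeping genes, and rapidly evolving surface, lysosomal and immune genes) was written after the Ctrl column had been seen and before the lists were measured. Some of their members also stood in the 30 lists.

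The rule for named genes, set before the data were examined, took per comparison the 10 highest and 10 lowest genes past the filter without predicted or clone-named loci, per list up to 4 members 2-fold apart from Ctrl with the largest differences (or up to 2 where none was), and always Mir17hg, Mcm7, Bcl2l11, E2f1, Tgfbr2 and Map3k2. It named 153 genes. List members 2-fold apart between Hi and Med, the reported target lower than Ctrl, and members named for the added lists, were chosen after their values were seen. The planned rule also always names some further reported targets, which are not analysed here. The planned search for target sites of the cluster's microRNAs was not run, because 3' UTR sequences were not used here.

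Alternatives tried were no filter, a stricter filter at the 75th percentile of mean levels (8.43), centring of each column on its median, quantile normalization, a loess of the difference on the mean level (span 0.3), the brightest probe set per gene, genes with 1 probe set, thresholds of 1.5-fold and 3-fold, random lists without matching, and list means in place of medians. Leaving out probe sets that are identical in Med and Hi was added after the data had been seen. The counting and list steps were tested on simulated data for Hi against Med with 9969 genes and 200 of them changed. At 1.5-fold 6% of the changed genes were called, at 2.5-fold 81% and at 4-fold 100%, with 5, 3 and 7 unchanged genes called. Of 20 lists shifted by 0.3, 20 stood above the random lists, and of 20 unshifted lists 3 stood outside them. The simulated columns held no identical values, unlike the deposited Med and Hi columns. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used. For arrays the depth is set by signal over background, and 1 column per group limits the precision.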

Results

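Expression was measured in CT26 mouse colon carcinoma cells that carried a control microRNA vector (miR-Ctrl, here Ctrl) or the miR-17~92 cluster at a medium (miR-17~92Med, Med) or high level (miR-17~92Hi, Hi). The cluster encodes the precursors of miR-17, miR-18a, miR-19a, miR-20a, miR-19b and miR-92a. Each group had 1 column of log2 values over 35556 probe sets. There were no replicate columns, so no difference below has a measured error, and higher or lower describes these columns alone. Column medians were 6.95 in Ctrl, 6.65 in Med and 6.66 in Hi, and the interquartile ranges were 2.42, 3.12 and 3.08. Genes with a level above 12 numbered 30 in Ctrl, 162 in Med and 162 in Hi.

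The array gave no check of the labels from the transfected locus. The host transcript Mir17hg was at 5.98 in Ctrl, 6.02 in Med and 6.02 in Hi, below the expression filter. The probe set of the precursor Mir17 was at 5.55, that of Mir20a at 4.29 and that of Mir19b-1 at 5.46 in every column. The Mir18 probe set was at 7.87, 6.74 and 6.77, and that of Mir19a at 6.50, 4.72 and 4.73. A probe set shared by Mir92-1 and Mir17hg was at 7.41, 6.71 and 6.71. The Mir18, Mir19a and shared Mir92-1 probe sets were thus lower in both miR-17~92 columns than in Ctrl, against the direction of the labels. Receptor genes at background were lower there too, with medians of 4.92 in Ctrl and 4.51 in Med and Hi. How far these probe sets speak against the labels is therefore unknown. Probe sets for small precursors do not read mature microRNAs, and no probe set of the locus was higher in Hi than in Med by more than 0.04. Of the paralogous hosts, Mcm7, a replication helicase gene that carries the miR-106b~25 cluster in an intron, was at 8.27 in Ctrl and 9.70 in both others, a difference that is under 2-fold once columns are centred (0.83 for Med, 0.89 for Hi). Mir25 was at 9.09, 7.60 and 7.60. Of the 11 genes of this list, 3 passed the filter.

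The first question was which genes differ between cells with the cluster and the control line. Ifitm3, mitochondrial RNAs and B2m were among the genes highest in both miR-17~92 columns. Ifitm3, an interferon-induced membrane protein, was at 5.20 in Ctrl, 13.08 in Med and 13.04 in Hi. B2m, the light chain of MHC class I, was at 6.19, 13.20 and 13.15. Also among the highest were the lysosomal membrane gene Lamp2 (4.62, 10.76 and 10.76), the tetraspanin Cd63 (5.78, 11.86 and 11.81) and the small nucleolar RNA Snord82 (4.42, 11.46 and 11.61). The zinc finger gene Zfp971 (3.32, 9.86 and 9.62) was another. The interferon-induced Ifi203 (5.78, 12.26 and 11.74) was among the 10 highest in Med alone. Among the 10 highest in Hi were also Emb (5.75 in Ctrl, 11.91 in Hi) and the nuclear RNA Malat1 (6.24 and 12.31). The mitochondrially encoded COX2 (cytochrome oxidase, not Ptgs2) was at 6.00, 13.40 and 13.31, and ND3 was at 5.07, 12.49 and 12.21.

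Tmsb4x, Pfn2 and Acta2 were among the genes lowest against Ctrl. Tmsb4x, which binds actin monomers, was at 11.25 in Ctrl, 5.39 in Med and 5.66 in Hi. The profilin Pfn2 was at 10.55, 6.95 and 7.24, the smooth muscle actin Acta2 at 9.67, 6.42 and 6.42, and the gamma tubulin Tubg2 at 9.83, 6.63 and 6.63. The heparan sulfate polymerase Ext1 was at 10.86, 7.47 and 8.45, the let-7 precursor Mirlet7i at 9.83, 7.01 and 7.20, and the antizyme Oaz2 at 10.69, 8.46 and 8.02. Plpp4, Apold1, Ebf3 and Rab6b completed the lowest genes, each between 9.02 and 9.65 in Ctrl and between 6.19 and 6.81 in the others.

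Of the 9969 genes past the filter, 3475 were at least 2-fold higher and 867 at least 2-fold lower in Med than in Ctrl, together 4342 (43.6%, of which 80.0% higher). In Hi against Ctrl, 3335 were higher and 837 lower, together 4172 (41.8%, of which 79.9% higher). Under quantile normalization the split was 2485 higher and 1875 lower for Med, and 2450 higher and 1781 lower for Hi. With centred columns it was 2282 and 1746 for Med, and lower genes numbered 1637 for Hi. The median difference of genes past the filter was 0.42 for Med and 0.39 for Hi, and centring lowers every difference by 0.60 for Med and 0.54 for Hi. The Ctrl column correlated with Med at r = 0.787 and with Hi at 0.795 across probe sets, and Med with Hi at 0.992 (genes are not independent replicates). Over the 7 probe sets annotated to mitochondrially encoded mRNAs, Ctrl lay between 4.32 and 6.16 and Hi between 8.87 and 13.42, a median difference of 7.10. Receptor genes, a gauge of background, had medians of 4.92 in Ctrl and 4.51 in Med and Hi (SD over genes 1.08, 0.93 and 0.94). Levels near these may be background, so the size of a difference from them is not known.

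**Figure D1:**
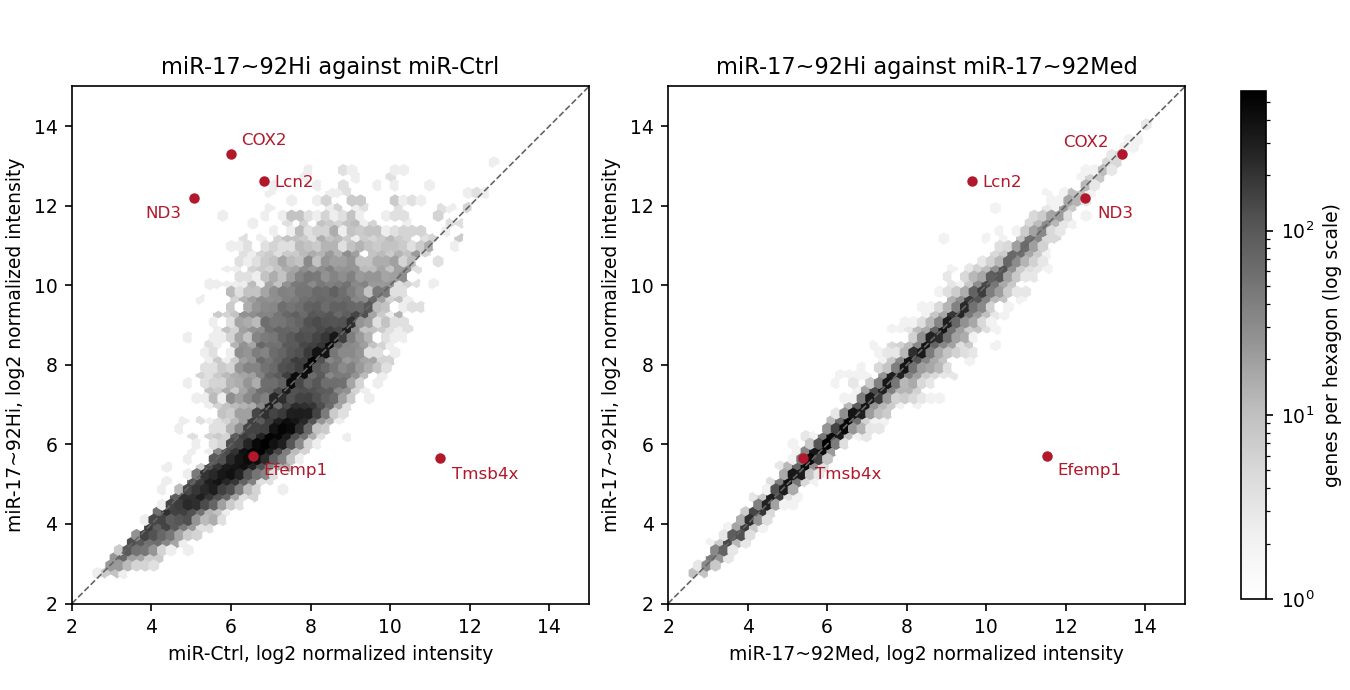
Gene levels in miR-17~92Hi (vertical axis) against miR-Ctrl (left) and against miR-17~92Med (right), both in log2 normalized intensity, with darker hexagons for more genes (log scale), the dashed line at equal levels, and 5 genes marked. The mitochondrial COX2 is at 6.00 in miR-Ctrl and at 13.31 in miR-17~92Hi, while Efemp1 lies on opposite ends in the miR-17~92 columns, at 11.52 and 5.70.

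Of the gene lists, interferon response genes stood furthest above Ctrl. Rapidly evolving surface, lysosomal and immune genes lay low in Ctrl as a class, as given further below. How far the differences from Ctrl in this paragraph show an effect of the cluster is therefore unknown. In the interferon list, 21 of 23 members past the filter were at least 2-fold higher and none lower, with a median difference of 3.48 in Med and 2.91 in Hi (random lists 0.18 to 1.53 in Hi). With centred columns the medians were 2.88 and 2.37. Usp18, a brake on interferon signalling, was at 6.97, 12.56 and 11.75 in Ctrl, Med and Hi, Irgm1 at 5.74, 11.17 and 10.56, Ifit1 at 6.45, 11.30 and 10.67, and Ifit3 at 5.38, 11.48 and 10.39. Antigen presentation genes lay inside the random range, with 8 of 15 higher by 2-fold and a median of 1.36 in both, among them Canx (8.97, 12.84 and 12.84), Tapbp (8.13, 11.08 and 11.33) and the immunoproteasome gene Psmb10 (8.11, 9.65 and 10.15), the last under 2-fold for Med under centring, quantile and loess scaling (0.94, 0.91 and 0.85). NK cell ligand genes had 5 members past the filter, 3 of them 2-fold higher and 1 lower, and medians of 2.37 and 2.17, above the random lists. The NKG2D ligand H60b (6.27, 8.63 and 8.44), the DNAM-1 ligand Pvr (6.73, 10.48 and 9.65) and Clec2d (5.58, 9.86 and 8.23) were higher than in Ctrl and the adhesion molecule Icam1 (8.34, 7.05 and 7.14) was lower.

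Mitotic genes and oxidative stress genes also stood above the random lists in both columns. Of 21 mitotic genes, 15 were 2-fold higher in Med (median 1.70) and 15 in Hi (1.34), the Hi value lying inside the random range under loess scaling (0.74). The checkpoint kinase Bub1 was at 5.49, 10.25 and 8.81, the motor Kif11 at 6.31, 9.40 and 8.74, Tpx2 at 6.06, 9.34 and 9.22, and the proliferation marker Mki67 at 6.85, 9.98 and 9.58. Of 22 oxidative stress genes, 16 were 2-fold higher in each, with medians of 2.07 and 1.94, including Gstp1 (6.14, 11.99 and 12.08), the regulator Nfe2l2 (7.86, 11.91 and 11.78) and the peroxiredoxin Prdx1 (7.96, 11.55 and 11.47). Matrix protease and motility genes were at percentile 99.3 in Med, outside the central range, and at 95.9 in Hi, inside it, with centred medians of 1.40 and 1.10. Under quantile and loess scaling the Med median lay inside (0.86 and 1.07), and the Hi median above (1.20 and 1.17). Among the members higher than Ctrl were Itgb1 (6.94, 11.24 and 10.90), Cd44 (6.10, 9.81 and 9.39), Cdc42 (8.57 in Ctrl and 12.13 in Med) and Itga6 (8.30, 11.21 and 10.25). Cholesterol and fatty acid synthesis genes were at percentile 99.4 in Hi (median 1.61) and 96.5 in Med (1.44, inside), and by list means above in both columns (percentile 98.5 in Med). Differences between Med and Hi in the placing of these lists were not tested. Of 23 cholesterol and fatty acid genes 13 were 2-fold higher in each column, among them the desaturases Scd1 (6.71, 11.22 and 11.22) and Scd2 (7.77, 11.55 and 11.82), Msmo1 (6.40, 10.44 and 10.82) and the squalene synthase Fdft1 (6.97, 10.06 and 10.48).

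Chemokine and NF-kB genes stood above in Hi, with a median of 2.22 (random lists 0.00 to 1.38), and inside in Med, with a median of 0.49. Of 19, 11 were 2-fold higher in Hi and 8 in Med. The prostaglandin synthase Ptgs2 was at 8.26, 12.06 and 11.70, and Ccl2 at 7.48, 10.07 and 10.93. Endothelial and fibroblast markers stood below in both, with 5 of 6 members 2-fold lower and medians of -1.23 and -1.21. The collagens Col1a1 (8.76, 7.44 and 7.57) and Col1a2 (8.60, 7.29 and 7.37) were among them, while the receptor Pdgfra was higher (7.26, 9.79 and 10.27). Extracellular matrix genes had medians of -0.07 and -0.15, below the random lists, but means of 0.60 and 0.64, and lay inside under quantile and loess scaling. Of 18, 7 were 2-fold higher and 4 lower in Med, and 8 higher and 5 lower in Hi. Fibronectin (Fn1, 8.69, 13.45 and 13.32), Lamb1 (8.29, 11.42 and 11.30), Timp2 (9.87, 12.57 and 12.43) and Timp1 (7.83, 10.43 and 9.76) were among the higher ones. MAPK and immediate-early genes had a median of 0.01 in Med and 0.00 in Hi, the latter below the random lists and inside under quantile and loess scaling (-0.43 and -0.19). Of 22, 6 were 2-fold higher and 4 lower in Hi, with Jun (7.85, 11.05 and 10.25) and Ier3 (7.16, 9.96 and 9.61) higher and Egr3 (9.65, 7.74 and 7.71) lower. Lists outside the central 95% numbered 7 of 28 in Med and 9 of 28 in Hi, where the nominal chance number is 1.4. Some lists share genes, and the list step was not simulated for the comparisons with Ctrl. The Ctrl column stood beside each of these lists with its mitochondrial mRNAs between 4.32 and 6.16.

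**Figure D2:**
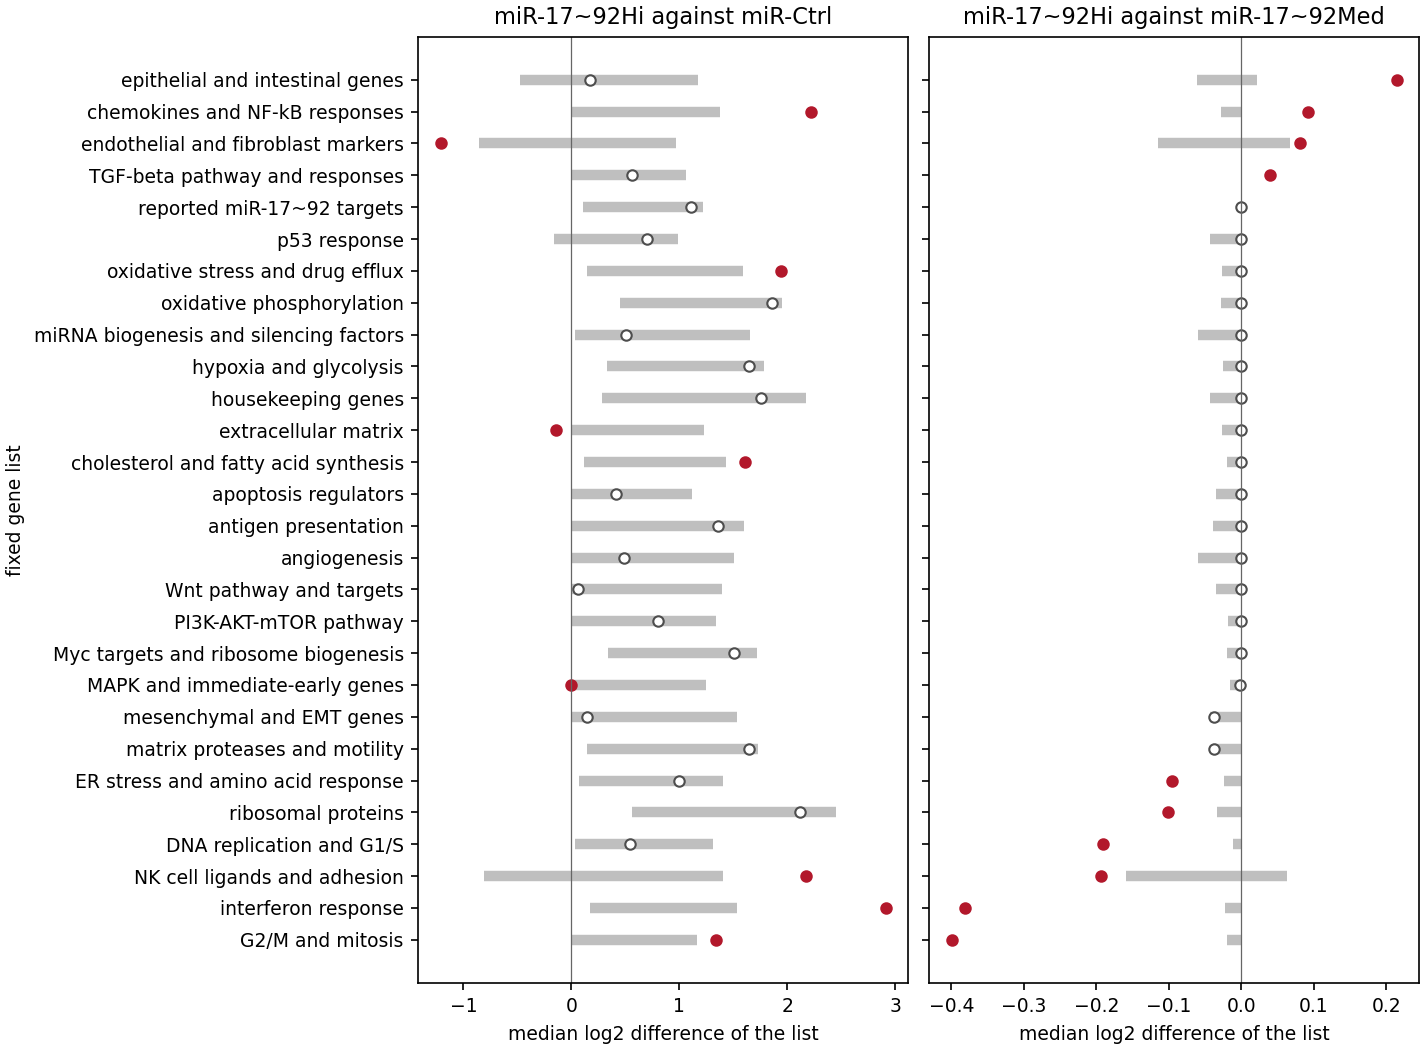
Median log2 difference of each of the 28 gene lists with at least 5 members past the filter (points) in miR-17~92Hi against miR-Ctrl (left) and against miR-17~92Med (right), with grey bars for the central 95% of 10000 random lists matched on mean level and filled points for lists outside it. Against miR-Ctrl the interferon list has a median of 2.91, and against miR-17~92Med the mitotic and interferon lists have medians of -0.40 and -0.38.

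The study's title speaks of predicting targets of the cluster, and reported targets were compared as a list. Their medians did not lie below the random lists in either column. Both comparisons rest on the Ctrl column, and how far they show the cluster's effect is unknown. The random range is wide, so a small lowering of the targets is not excluded. Of 33 members past the filter, 15 were at least 2-fold higher and 1, E2f2 (8.59 in Ctrl, 7.21 in Med and 7.12 in Hi), lower in Med than in Ctrl, with a median of 0.80 (percentile 69.9, random lists 0.12 to 1.29). In Hi 17 were higher and 1 lower, with a median of 1.11 (percentile 94.8), or 0.57 with centred columns. The pro-apoptotic Bcl2l11 was at 8.34 in Ctrl, 10.02 in Med and 9.74 in Hi, differences under 2-fold with quantile normalization (0.93 and 0.71). E2f1 was at 8.60, 9.03 and 8.91, Tgfbr2 at 8.66, 9.15 and 8.66, and Map3k2 at 7.89, 8.23 and 8.23. For E2f1 and Map3k2 the sign against Ctrl turns with centred columns (-0.23 and -0.19 in Hi), as it does for Tgfbr2 in Med (-0.10). Ccnd2 (8.58, 11.11 and 10.85) and Nfat5 (8.31, 10.60 and 10.87) were 2-fold higher in both columns, and Thbs1 (9.38, 10.24 and 11.87) and Txnip (8.71, 9.01 and 11.12) in Hi.

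A graded design asks whether Med lies between Ctrl and Hi. Of the 3335 genes 2-fold higher in Hi than in Ctrl, Med was strictly between in 940 (28.2%), identical to Hi in 765 and beyond Hi in 1614. Of the 837 genes lower in Hi, Med was between in 186 (22.2%), identical to Hi in 238 and beyond Hi in 409. Leaving out genes in which Med was identical to Hi or Ctrl, the shares were 36.6% and 31.1%. Lcn2 (6.82, 9.65 and 12.63) and Cxcl5 (6.88, 10.75 and 12.65) were among genes with Med between, and Ifit3 among those with Med beyond Hi. The genes higher than Ctrl in both columns numbered 3207 (1163 in independent lists), and those lower in both 811 (72.8). The 2 differences from Ctrl correlated at 0.976 across genes, where simulated unchanged columns with a shared control gave 0.50. Their covariance was 1.65 and the simulated one 0.0413. The simulation gave Ctrl the same spread as Med and Hi, and both overlaps use the same Ctrl column. A Ctrl column that lies apart from both could therefore make all of the excess, which cannot be split.

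Hi against Med compares both levels of the cluster, and the Ctrl column is not part of the difference. Ctrl still entered the mean level that set the expression filter and the matching of random lists. Genes furthest higher in Hi included Ogn, Dhrs3 and Lcn2, and the gene furthest lower was Efemp1. Ogn, a secreted proteoglycan, was at 6.68 in Med and 9.96 in Hi, the retinal reductase Dhrs3 at 6.65 and 9.82, the iron-siderophore binder Lcn2 at 9.65 and 12.63, and the serum protein gene Fetub at 6.47 and 9.39. The aldehyde dehydrogenase Aldh3a1 (8.40 and 11.16), Bpifb4 (6.28 and 9.02), the serum amyloid Saa3 (7.80 and 10.48), the chemokine Ccl20 (6.22 and 8.79), the carbonyl reductase Cbr2 (7.14 and 9.65) and the microtubule binder Eml1 (6.56 in Med and higher by 2.43) followed. The matrix protein gene Efemp1 was at 11.52 in Med and 5.70 in Hi, and at 6.56 in Ctrl. The ligand Wnt1 (9.63 and 6.14), the urea transporter Slc14a1 (10.36 and 7.82), Ly6e (13.27 and 10.93), the anthrax toxin receptor Antxr1 (9.49 and 7.21), Arhgdib (9.24 and 6.97), cyclin B2 (Ccnb2, 9.56 and 7.29), the gap junction gene Gja1 (11.55 and 9.44), Dynap (10.26 and 8.44) and Stxbp5 (10.25 and 8.48) were also lower.

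Of 9969 genes, 68 were at least 2-fold higher and 86 lower in Hi than in Med, together 154 (1.54%). With quantile normalization the counts were 53 and 47. Among 1194 olfactory and vomeronasal receptor genes 0 were 2-fold apart, with an SD over genes of 0.09, against 82 (6.87%) in Med against Ctrl and 77 (6.45%) in Hi against Ctrl. Med and Hi held identical values in 15551 probe sets (43.7%), and in 45.9% of the genes past the filter. Random lists therefore had medians close to 0, and small list medians stood outside them.

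**Figure D3:**
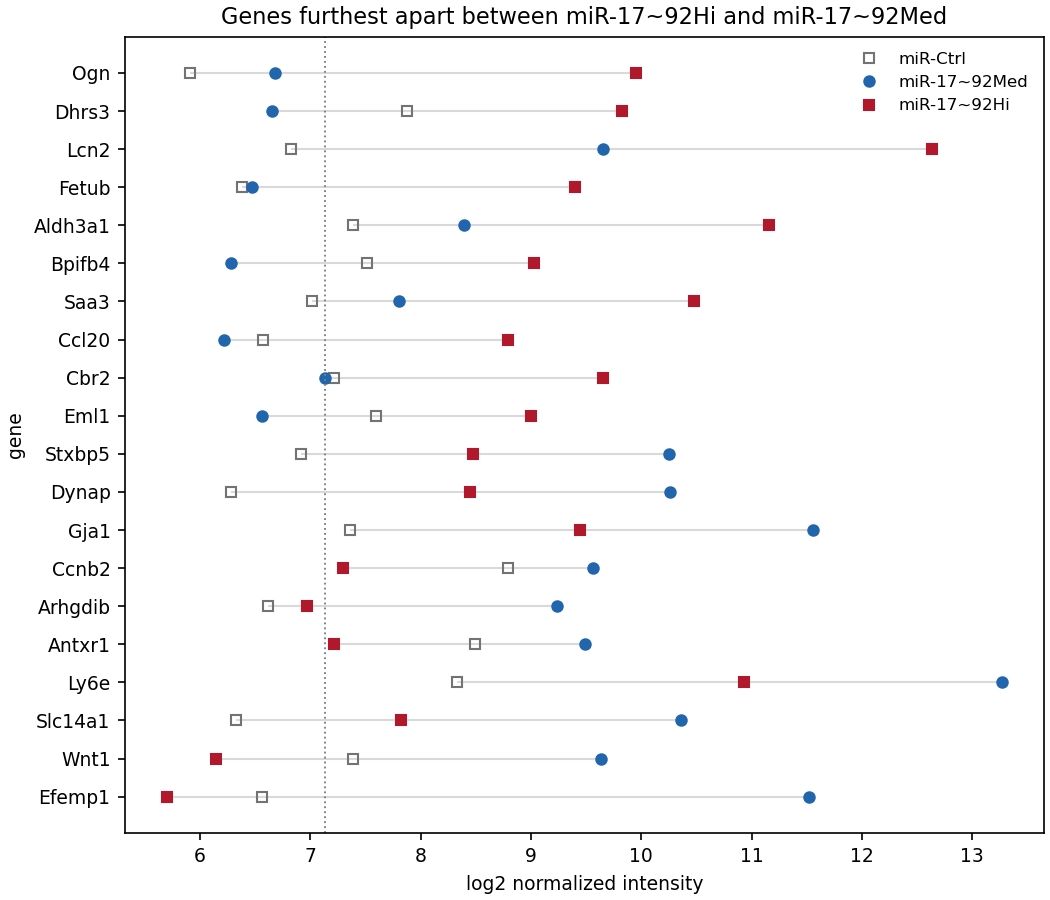
Levels of the 10 genes highest and the 10 lowest in miR-17~92Hi against miR-17~92Med (vertical axis), in log2 normalized intensity, in miR-Ctrl (open squares), miR-17~92Med (circles) and miR-17~92Hi (filled squares), with a dotted line at the expression filter of 7.13 and grey lines joining the lowest and highest value. Efemp1 is at 11.52 in miR-17~92Med and at 5.70 in miR-17~92Hi, and Lcn2 is at 9.65 and 12.63.

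Genes of the cell cycle were lower in Hi than in Med as groups. Of 21 mitotic genes 19 were lower, 2 identical and none higher, with a median of -0.40 (random lists -0.02 to 0.00). Ccnb2 (-2.27) and Bub1 (-1.44) were 2-fold lower, Kif11 differed by -0.67 and Mki67 by -0.40. Of 23 DNA replication genes 15 were lower, 8 identical and none higher, with a median of -0.19, and none was 2-fold apart. Mcm6 differed by -0.56, the clamp gene Pcna by -0.44 and the reductase Rrm1 by -0.35. Interferon response genes were lower too, 20 of 23, with a median of -0.38. Ifit2 (-1.15), Ifit3 (-1.08) and Gbp7 (-1.07) were 2-fold lower in the deposited values and under 2-fold with quantile normalization (-0.99, -0.99 and -0.92), and Usp18 differed by -0.81. The medians of these 3 lists stayed below the random lists under every alternative tried.

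Chemokine genes were higher in Hi than in Med, 11 of 19 with 3 lower and 5 identical, with a median of 0.09 and a mean of 0.60. Ccl20 (2.57), Cx3cl1 (2.23), the granulocyte factor Csf3 (8.20 in Med and 10.20 in Hi), Cxcl5 (1.90) and Cxcl1 (1.06) were 2-fold higher. TGF-beta genes had a median of 0.04 and a mean of 0.15, with 13 of 25 higher and 9 lower. Thbs1 (1.63), Ccn2 (1.23), Tgfb2 (1.11) and Ltbp2 (1.11) were 2-fold higher, Tgfb2 under 2-fold with quantile normalization (0.96). Epithelial genes were higher in 8 of 9, with a median of 0.21 and none 2-fold apart, led by the keratin Krt18 (0.87). Endothelial and fibroblast markers had a median of 0.08 and lay inside the random range with quantile normalization.

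Of 22 ribosomal protein genes 19 were lower in Hi, with a median of -0.10 and a mean of -0.11, the mean lying inside the random range. The widest of their named members, Rpl7, differed by -0.21. Of 23 ER stress and amino acid genes 14 were lower, with a median of -0.10, among them Cth (-1.44), an enzyme of cysteine synthesis, and the asparagine synthetase Asns (-0.48). The NK cell ligand list had a median of -0.19 over 5 genes, with Clec2d at -1.63 and Pvr at -0.83. Reported targets had a median of 0.00, with 8 higher, 11 lower and 14 identical of 33. Txnip (2.11), App (1.76), Thbs1 (1.63) and Ccn2 (1.23) were 2-fold higher and none was 2-fold lower, and their mean of 0.12 stood above the random lists. Lists outside the central 95% numbered 10 of 28, with 4 above and 6 below. The nominal chance number is 1.4, but in the simulation of this comparison 3 of 20 unshifted lists lay outside. That simulation held no identical values, so its share need not hold for these columns. Without the probe sets identical in Med and Hi, an alternative added after the data had been seen, the medians were -0.40 for mitosis, -0.35 for DNA replication, -0.43 for interferon response and 0.52 for chemokines, and those of the NK cell ligand and the endothelial and fibroblast lists lay inside. The mesenchymal list (-0.26) then stood below, and the angiogenesis (0.21) and cholesterol (0.24) lists above. With all probe sets, the cholesterol list had a median of 0.00 in Hi against Med, with 11 of 23 higher and 6 lower, and stood above by its mean of 0.18 and under loess scaling.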

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

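The tests of signal range, of a response to the cluster, of another mouse sample and of identical values were chosen after the result was seen. That of another organism was set after the Ctrl column had been seen to lie apart and before its added lists were measured. Some members of the added lists also stood in the earlier lists, so it is not independent of the pattern.

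In 4 genes Med and Hi lay on opposite sides of Ctrl by at least 2-fold each, a difference between the groups that was not tested. Bpifb4 was at 7.52 in Ctrl, 6.28 in Med and 9.02 in Hi (Hi minus Med 2.74), Dhrs3 at 7.88, 6.65 and 9.82 (3.17), and Eml1 at 7.59 in Ctrl, 6.56 in Med and above Ctrl by 1.40 in Hi (2.43). Wnt1 was at 7.38, 9.63 and 6.14 (-3.49). Each falls under 2-fold on one side with loess scaling (Med minus Ctrl -0.54, -0.75 and -0.42 for the first 3, Hi minus Ctrl -0.54 for Wnt1), as do Bpifb4 and Eml1 in Hi minus Ctrl with centred columns (0.97 and 0.86). Probe sets with no gene name here entered no comparison. Of the 3795 past the filter, 1154 were at least 2-fold above Ctrl in both Med and Hi. Among named genes it was 3207 of 9969, a similar share, so the count is not particular to unnamed probe sets.

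The Ctrl column differed from Med and Hi by far more than these from each other. A narrower signal range of that array does not account for all of it, since quantile normalization left 42.3 times as many genes 2-fold apart between Hi and Ctrl as between Hi and Med. A response of the cells to the cluster as the whole cause is argued against by mitochondrially encoded mRNAs, which mouse cell lines use throughout. The same holds for mouse RNA of another cell type as the whole cause. Without COX2 and ND3, top genes of the pattern, the other 3 probe sets were lower in Ctrl by 4.55 to 7.81, with a median of 7.07. They are of ATP6 and ND6, each shared with a nuclear gene. As all are encoded in the same mitochondrial genome, these are not independent of COX2 and ND3. RNA of another organism on the Ctrl array remains open. Slowly evolving housekeeping genes lay above genes of the same level in Med and Hi by a median of 1.34 (67 genes, 18 of them below). Rapidly evolving genes lay below by -0.85 (57 genes, 11 of them above), a difference of 2.19. Ywhaz, at 12.14 in Ctrl and 11.29 in Med, and Ctsl, at 7.92 and 13.68, were among the widest. This measure is relative, and the levels of most slowly evolving genes were lower in Ctrl than in Med. Arf1, at 10.07 in Ctrl and 12.18 in Med, still lay above genes of the same level by 0.54. The slowly evolving Eef2 went the other way, at 9.53 and 13.36. The earlier lists give no such contrast. Ribosomal proteins were lower in Ctrl than in Med in 21 of 22 genes, and housekeeping genes in 16 of 17. Their medians against Ctrl in Med, 2.20 and 1.74, lay inside the random range. Those random lists were matched on the mean of all columns, so the measures are not alike. These lists also differ in what their genes do, the organism cannot be named from them, and a mix of these explanations was not tested, so how far the comparisons with Ctrl show the cluster's effect is unknown.

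Identical values were the second pattern: 15551 probe sets (43.7%) were the same in Med and Hi, and 2815 (7.92%) in all columns. In 2.13% of probe sets Ctrl was identical to exactly 1 other column, ties that a median polish of 3 arrays, in which the effects of several arrays can be exactly 0, may have made. A polish simulated at an assumed probe noise with 1 array per group gave Ctrl identical to Med in 8.30% of sets (8.75% seen), Ctrl to Hi in 8.10% (9.21% seen) and Med to Hi in 14.7%, and with 3 arrays per group averaged 0% in each pair. At assumed settings this neither explains nor excludes the larger share seen for Med and Hi, nor does it settle how many arrays a column holds. Part of one array entered a second time stays open for the ties of Med and Hi, since ties with Ctrl elsewhere say nothing about them and no other value decides it.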

How the results depend on the processing

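All alternatives below were set before the data were examined, except leaving out probe sets identical in Med and Hi. No paired analysis was possible because each group had 1 column, and no replicate could be left out for the same reason. The planned search for target sites was not run, as 3' UTR sequences were not used. Counted over the named genes, the comparisons and the settings, 3399 differences kept their side of the 2-fold line, 68 went under it and 13 past it, and none at 2-fold or more changed sign. For list medians, 655 kept their place relative to the random lists, 30 moved inside and 59 moved outside. The cause of the differences below was not tested, apart from filters and thresholds, which change the genes counted. Without a filter 6911 genes were 2-fold apart in Med against Ctrl (3256 lower) and 6562 in Hi against Ctrl (3077 lower). The stricter filter left 2577 (126 lower) and 2514 (126 lower), and 68 in Hi against Med (33 higher, 35 lower). Centring gave 2282 higher and 1746 lower in Med and 1637 lower in Hi against Ctrl. Quantile normalization gave 1875 lower in Med and 1781 in Hi against Ctrl, and 100 genes (47 lower) in Hi against Med. At 1.5-fold, 1460 genes were lower in Med and 1448 in Hi against Ctrl, and 519 were apart in Hi against Med (172 higher, 347 lower). At 3-fold, 2481 were apart in Med against Ctrl (2305 higher, 176 lower), 2289 in Hi against Ctrl (2147 higher, 142 lower) and 42 in Hi against Med (27 higher, 15 lower). Med lay between in 25.7% of genes higher in Hi and 19.1% of those lower at 1.5-fold. Lists above the random range in Med against Ctrl numbered 11 without matching and 8 by means, and lists below it 0 with the stricter filter and 1 each with quantile normalization, loess and means. In Hi against Ctrl, lists above numbered 10 with quantile normalization and 14 without matching, and lists below 0 with the stricter filter and 1 each with quantile normalization and loess. Dim genes limit the array: receptor genes had a median of 4.92 in Ctrl and 4.51 in Med and Hi, and were 2-fold apart from Ctrl in over 6% without any replicate to gauge it.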

Other observations

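The tests of copy number, of neighbouring genes and of receptor noise were set before their results were seen.

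Several lists not yet described against Ctrl lay inside the random range in both columns while most of their members were higher than in Ctrl. Under quantile normalization the lists of oxidative phosphorylation and of Myc targets stood above it in both columns, that of hypoxia and glycolysis in Hi (under loess too) and that of ribosomal proteins in Med. By list means, those of oxidative phosphorylation, Myc targets and ribosomal proteins stood above it in both columns. Of 24 hypoxia and glycolysis genes 16 were 2-fold higher in each column (medians 1.80 and 1.64), among them Pgk1 (8.35, 12.61 and 12.61 in Ctrl, Med and Hi), Ldha (9.28, 13.30 and 13.36), Pfkp (6.15, 9.46 and 9.52) and Egln3 (8.40, 11.48 and 10.71). Of 23 oxidative phosphorylation genes 19 were (1.74 and 1.86), such as Cox6c (8.30, 12.44 and 12.96), Atp5c1 (8.86, 12.86 and 12.84), Atp5b (9.60, 13.16 and 13.09) and Ndufa9 (6.40, 9.98 and 9.98). Of 24 Myc targets and ribosome biogenesis genes 18 were in Med and 17 in Hi (1.55 and 1.51), with Odc1 (6.02, 11.41 and 10.97), Npm1 (6.98, 12.31 and 11.96), Ncl (7.05, 11.93 and 11.93) and Hspd1 (7.23, 11.12 and 11.18), and Myc itself at 8.48, 12.21 and 12.06. Ribosomal proteins had medians of 2.20 and 2.12, with Rps6 at 9.15, 13.74 and 13.63, and housekeeping genes had 1.74 and 1.75, with Rplp0 at 10.28, 12.87 and 12.83 and Rab7 at 8.30, 11.70 and 11.57. DNA replication genes had 0.80 and 0.54, with Pcna at 7.27, 11.66 and 11.22, and ER stress and amino acid genes 1.18 in Med, with 12 of 23 2-fold higher in Hi, and with Hspa5 at 8.81, 11.85 and 11.91. The random lists at these levels also had medians well above 0, for instance 1.21 for housekeeping genes in Med.

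PI3K-AKT-mTOR genes had medians of 1.10 in Med and 0.81 in Hi against Ctrl, with Pik3ca at 7.18, 10.36 and 10.25 and Rictor at 7.01, 9.70 and 9.87. Apoptosis regulators had 0.69 and 0.41, with Casp8 at 6.50, 10.32 and 10.16, Cflar at 6.15, 9.11 and 8.35 and Mcl1 at 7.56, 10.02 and 10.02. MicroRNA biogenesis factors had 0.46 and 0.50, with Ddx17 at 7.93, 10.83 and 11.06 and Xpo5 at 7.54, 9.26 and 9.14. Angiogenesis genes had 0.43 and 0.49, with Nrp2 at 8.39, 11.26 and 11.18. TGF-beta genes had 0.10 and 0.57, with Ltbp1 at 8.34, 11.10 and 10.78 and the antagonist Bambi at 8.78, 6.45 and 6.40. Epithelial and intestinal genes had -0.40 and 0.18, with Krt18 at 7.97, 11.41 and 12.28 and Cdx1 at 8.95, 7.24 and 7.45. p53 response genes had 0.24 and 0.70, and between Hi and Med the death receptor Fas (6.96 in Med, 8.47 in Hi) and Plk2 (7.39 and 8.73) were 2-fold higher. Wnt genes had 0.26 and 0.06, with Ctnnb1 at 9.35, 11.75 and 11.75, and the feedback gene Axin2 lower in Hi (6.75) than in Med (8.44), alongside the ligand Wnt1. Mesenchymal genes had 0.15 and 0.15, and Cdh2 was lower in Hi (8.92) than in Med (9.95), by under 2-fold with quantile normalization (-0.88). The sterol genes Sqle (8.71 and 10.00) and Insig1 (9.99 and 11.21), the protease Mmp13 (7.17 and 8.41) and the glutathione transferase Gstm1 (10.12 and 11.24) were 2-fold higher in Hi than in Med. Of 19 immune cell markers measured 1 passed the filter, Cd68, at 7.18, 9.12 and 7.67.

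Differences between Hi and Med were correlated along chromosomes, over all genes past the filter with a known place and not only those 2-fold apart. Of receptor genes 0% were 2-fold apart, which argues against noise at background level, a median of 4.51 in Med and Hi. They do not gauge noise at the levels of genes past the filter, so noise there stays open. Adjacent genes correlated in Hi minus Med (Spearman 0.185 over 9303 genes, against -0.02 to 0.02 in 1000 shuffled gene orders) and in Hi minus Ctrl (0.128). Copy-number differences between the clones predicted the former. The correlation is not particular to copy number, and other causes that act over stretches of a chromosome were not tested. Related neighbours alone are argued against by genes 20 places apart, which still correlated at 0.117. The mean and median differences were -0.19 and -0.07 on chromosome 9, -0.14 and 0 on chromosome 10, and 0.14 and 0.05 on chromosome 15. Means on chromosomes 6, 17 and 18 were close to that of chromosome 10, at -0.12, -0.11 and -0.11, each with a median of 0. A part of Hi against Med may therefore be clonal, and a response to the level of the cluster stays open and untested.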
